A study of Elaeis guineensis with 2 samples.

How the data were processed

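Chromatin immunoprecipitation with sequencing (ChIP-seq) was applied to fruit of the African oil palm, Elaeis guineensis, in which EgAGL9 was overexpressed according to the labels. The series holds 2 samples, 1 library immunoprecipitated with an antibody against EgAGL9 and 1 input library made without antibody, so each group has 1 sample and no peak has a replicate check. The samples were grouped by the antibody named in their labels.

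The deposited data are 1 peak list, called once with the immunoprecipitate as treatment and the input as control, in the narrowPeak layout without a header. Per the submitters' processing notes, FastQC, BWA 0.7.8, MACS2 2.1.1, HOMER and ChIPseeker were used, with no parameters in the sources used here. The genome build is not given in the sources used here. Sequence names are RefSeq accessions, with the prefix NC_ for assembled chromosomes and NW_ for scaffolds, and coordinates are given here 1-based on those sequences. The deposited values per peak are the authors' own: the fold enrichment at the summit (a linear ratio of pileup to expected pileup), the −log10 p and the −log10 q at the summit, and an integer score. The deposited score equalled 10 times the −log10 q, cut to a whole number, in all 7919 peaks. The lowest deposited −log10 q was 1.30, a q of 0.0497, and the lowest −log10 p was 3.82. These values were used only within this list, to describe, rank, filter and compare peaks and to recover their pileups.

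The pileup behind each peak was recovered from the list. MACS2 compares the pileup of immunoprecipitate fragments at the summit with an expected pileup from the input under a Poisson distribution, and its fold enrichment adds a pseudocount of 1 to both. For each peak, the whole-number pileup was searched at which the deposited fold and the deposited p both held. A whole number was found for 7919 of 7919 peaks within 0.1 of the change that 1 more fragment would make, with a largest residual of 0.029. The expected pileups followed from it. Of the 7919 expected pileups, 6997 were whole multiples of 0.463, within a tolerance of 0.02 plus the rounding error of the deposited fold. A step of 0.463 is what 1 input fragment is worth if the input library was 2.16 times as deep as the immunoprecipitate and was scaled down to it. The lowest expected pileup, 2.36 fragments per base, was shared by 248 peaks and was taken as the genome-wide expected level. That level depends on settings of the call, such as the genome size, which are not given. Every multiple of it given here depends on them too. The steps of most of the remaining values were those of counting windows of 1000 and 10000 bp scaled to a fragment length of 191 bp, and such steps were matched for 652 peaks. The 6997 peaks are called here peaks whose expected pileup was set by the fragment-size window. MACS2 takes the largest of the window values and the genome-wide level as the expected pileup, so it cannot fall below that level. The depth of the libraries in reads is not known from the list. Whether duplicate reads were removed and whether reads were paired is not given in the sources used here. The input steps may therefore count read ends in place of fragments, and the depth ratio of 2.16 holds only if they count fragments. Intervals on pileups cover counting error only and are exact Clopper-Pearson intervals at 95% on the split of fragments between the libraries. These intervals take each counted fragment as independent, which duplicate reads would not be. Nor do they allow for the choice of peaks by the same counts. Intervals on medians are 95% bootstrap intervals over peaks from 2000 draws. Intervals on shares of peaks are exact 95% binomial intervals. They treat peaks as independent draws, which neighbouring peaks need not be, and do not measure a spread between samples.

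Peaks per chromosome were compared with even placement of all chromosome summits in 10000 draws, two-sided, with Benjamini-Hochberg adjustment over 16 chromosomes; this test and that of spacing redraw the positions of the summits and are called here position permutation tests. The plan was to place summits on the non-N bases of a genome of the list's build. As none was used here, each chromosome was taken to run from its first to its last summit, with any N bases between them included. Spacing was the median distance to the nearest other summit on sequences with 3 or more peaks, compared with 10000 draws in which the first and last summit of each sequence stayed and the others were placed evenly between them. Relations across peaks were Spearman correlations with 100000 permutations, or 10000 where the expected pileup was involved. To compare peaks at like input levels, they were split into 10 equal bins by expected pileup. Differences of medians used 10000 permutations, two-sided, in a family of 7 with Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. Peaks of one list are not independent replicates, so these p-values compare positions and values within the list and not biological samples. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

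The methods were tested on simulated data. Pileups were recovered exactly for 100% of 2000 simulated peaks. These were made with the formula that the recovery inverts, over a narrower range of folds than the list holds. The lowest and highest folds were therefore not covered. Each kind of set was simulated 40 times. The spacing test called 0% of evenly placed sets and 100% of clustered sets. The correlation test called 7.5% of unrelated and 100% of related sets. The chromosome test made any call in 2.5% of even sets. It found a chromosome raised 1.5 times in density in 97.5%. The clustered sets were more strongly clustered than the list, and the raised chromosome, NC_025996.1, was among the longer ones. These shares therefore do not give the power for weaker clustering or shorter chromosomes.

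The tests of peaks per chromosome, of spacing and of fold with width, their settings of a −log10 q or fold of at least 5, of merged intervals and of −log10 q in place of fold, and the rule for named peaks were fixed before the data were examined. The recovery of pileups, the comparisons that use the expected pileup, the comparison of chromosomes with scaffolds, the counts of close neighbours, the densest window, the comparison of folds between chromosomes, and the tests of spacing and of fold with width on chromosomes alone were added after. The peaks named are the 10 with the highest deposited −log10 q, and other peaks named are said to be chosen after their values were seen. The annotation of summits by gene feature, the search for CArG boxes (the A/T-rich element that MADS-domain proteins bind) and for enriched 6-base words, and the tests of fixed gene lists need a genome and annotation of the list's build and were not run here. The gene table used alongside was of assembly EG11, which the list does not name, so no gene name or gene coordinate was taken from it.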

Results

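The data describe which sites were enriched with an EgAGL9 antibody in oil palm fruit chromatin. EgAGL9 is named for AGL9 (SEPALLATA3) of Arabidopsis, a MADS-domain transcription factor of flower development, and the mesocarp of the oil palm fruit is the source of palm oil. The comparison was of 1 immunoprecipitate with 1 input library from fruit overexpressing EgAGL9, and it asks which genomic sites the factor occupied. The series holds no control immunoprecipitate, so binding by the factor cannot be told apart from unspecific enrichment. The deposited list held 7919 peaks on 3925 sequences. No intervals overlapped. As there were no replicates, no peak carries an error between samples, and errors given for single peaks are counting errors. Peaks were not assigned to genes here.

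Most peaks lay on scaffolds. Of the 7919 peaks, 6208 (78.4%, 95% exact interval 77.5 to 79.3%) were on 3909 NW_ scaffolds and 1711 (21.6%, 20.7 to 22.5%) on the 16 NC_ chromosome sequences. Sequence lengths were not used here, so whether scaffolds held more than their share of the assembly was not tested. A single peak was found on 2809 of the 3909 scaffolds, and the most on one scaffold was 21, on NW_011550949.1 between positions 168513 and 1744287. Scaffolds whose last peak ended before position 5000 held 2019 of the 6208 scaffold peaks (32.5%), and 939 scaffold summits (15.1%) lay in the first 1000 bp of their sequence. Peaks had a median width of 273 bp, with 5th and 95th percentiles of 195 and 534 bp and a range of 191 to 1244 bp.

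Enrichment over the input was modest at most sites. The median of the authors' fold enrichment was 2.66, with 5th and 95th percentiles of 1.77 and 4.27 and a highest value of 7.18. A fold of at least 5 was reached by 135 peaks (1.70%, 1.43 to 2.01%) and a fold of at least 4 by 654 peaks, while 1023 peaks (12.9%) had a fold under 2. All 135 peaks with a fold of at least 5 also had a −log10 q of at least 5, a level reached by 4873 peaks in all. The share with a fold of at least 5 was 1.75% (1.19 to 2.49%) on chromosomes and 1.69% (1.39 to 2.04%) on scaffolds, and these intervals overlap.

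The immunoprecipitate pileup behind a peak ranged from 10 to 5095 fragments over the summit base, with a median of 57. The expected pileup from the input had a median of 21.8, which is 9.24 times the genome-wide level of 2.36. Only 248 peaks (3.13%) were compared with the genome-wide level itself. A small share is favoured in advance, since the expected pileup is the largest of several values and noise in any window can only raise it. At 6592 peaks (83.2%, 82.4 to 84.1%) the expected pileup was over 2 times that level, and at 3804 (48.0%, 46.9 to 49.1%) it was over 10 times. The fragment-size window around the summit set the expected pileup at 6997 peaks (88.4%, 87.6 to 89.1%). Against that level, the expected pileup was therefore raised at most of the sites where the immunoprecipitate exceeded it. Small rises can come from noise under the rule of the largest value, and this was not separated. How far the expected pileup was raised depends on the settings behind the level.

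**Figure D1:**
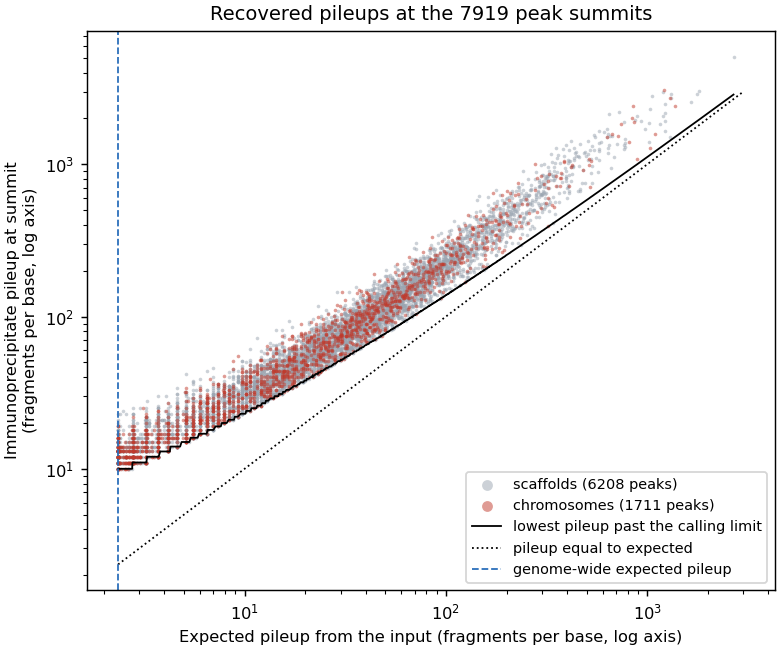
Immunoprecipitate pileup at the summit against the expected pileup from the input, both in fragments per base on log axes, with 1 point per peak on chromosomes (red) or scaffolds (grey). The solid line is the lowest pileup that passed the lowest deposited −log10 p, the dotted line equal pileups and the dashed line the genome-wide expected level of 2.36; every point lies above the dotted line.

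Fold enrichment was lower where the input was higher. Across peaks, fold and expected pileup had a Spearman rho of -0.68, and −log10 q and expected pileup a rho of 0.70 (permutation p = 0.0001 each, the smallest that 10000 permutations can give). Expected pileup is the denominator of fold, and the calling limit removes low folds at low input, which favours a negative rho in advance. At a given fold, −log10 q rises with expected pileup. These p-values are against a rho of 0 and do not test a relation beyond these links. In the lowest of 10 equal bins by expected pileup (792 peaks, at a median of 1.15 times the genome-wide level), the median fold was 3.87 (bootstrap 95% interval 3.87 to 3.90) and the median −log10 q 3.30. In the highest bin (792 peaks, at a median of 85.2 times), the median fold was 2.19 (2.15 to 2.25) and the median −log10 q 49.0. The fold needed to pass the calling limit depends on the expected pileup of each peak, and its median over peaks was 3.18 in the lowest bin and 1.26 in the highest.

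**Figure D2:**
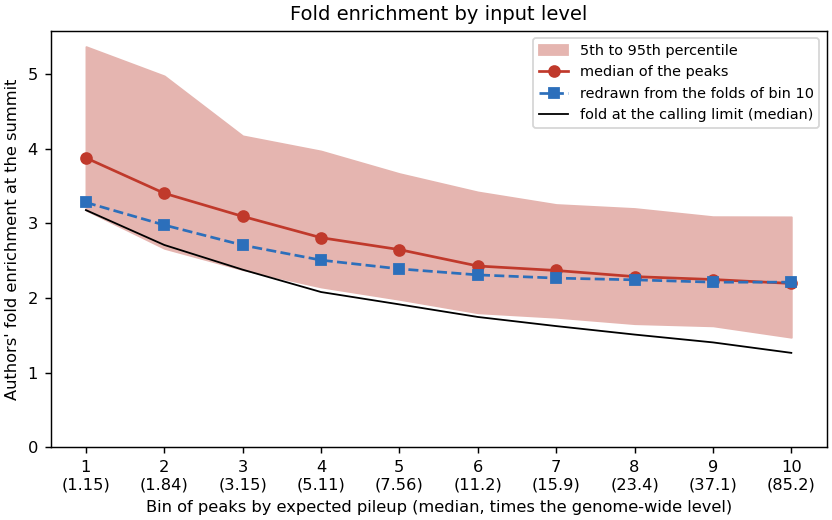
The authors' fold enrichment in 10 equal bins of peaks by expected pileup, with the median level of each bin (times the genome-wide level) in parentheses. Red points are medians, the band spans the 5th to 95th percentile of peaks, the black line is the median over the peaks of a bin of the fold needed to pass the calling limit, and the blue squares are medians redrawn from the folds of the highest bin; the observed median falls from 3.87 in bin 1 to 2.19 in bin 10.

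The 10 peaks with the highest −log10 q, from 300.3 to 460.6, were sites of very deep coverage in both libraries. Their folds ran from 1.90 to 3.62, and their expected pileups from 150 to 1139 times the genome-wide level. Of the 10, 8 were on scaffolds and 2 on chromosomes. Input fragments given below are counts of the step of 0.463, and whether that step is a fragment or a read end is not known. If duplicate reads were kept, the intervals below are too narrow. The first was peaks4440 on NW_011552430.1 (7196 to 7893, summit 7409), with 2144 immunoprecipitate fragments against 1393 input fragments, a depth-scaled ratio of 3.32 (exact 95% interval 3.11 to 3.56). The highest on a chromosome was peaks447 on NC_025995.1 (31496130 to 31496463, summit 31496301), with 3094 against 2616 fragments and a ratio of 2.55 (2.42 to 2.69). The other on a chromosome was peaks188 on NC_025994.1 (2989087 to 2989351, summit 2989231), with 2429 against 1839 fragments and a ratio of 2.85 (2.68 to 3.03). The deepest site of the list was peaks3310 on NW_011551409.1 (58389 to 58592), with 5095 against 5790 fragments and a ratio of 1.90 (1.83 to 1.97). The largest ratio among the 10 was 3.62 (3.31 to 3.97), at peaks3781 on NW_011551738.1 (101388 to 101737). The remaining 5 were peaks5365 on NW_011554612.1, peaks5559 on NW_011555341.1, peaks7294 on NW_011580734.1, peaks3322 on NW_011551413.1 and peaks5111 on NW_011553825.1, with folds of 2.66, 3.03, 2.49, 3.42 and 2.20.

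The peaks with the highest fold were a separate set, chosen here after their values were seen. All 10 lay on scaffolds, which held 78.4% of all peaks. Their folds ran from 6.48 to 7.18, resting on 21 to 42 immunoprecipitate fragments and an expected pileup of 1 to 2.16 times the genome-wide level. Their summit positions ran from 286 to 1414226. Some lay so close to the scaffold start, as at 286 in peaks6255 and 814 in peaks6962, that a window of 10000 bp would run past it. Whether this lowered their expected pileup was not tested. The highest was peaks6962 on NW_011574803.1 (524 to 964), with a pileup of 24 against 2.48 expected. The best covered was peaks6319 on NW_011563488.1 (1760 to 2055), with 42 against 11 input fragments and a depth-scaled ratio of 8.24 (exact 95% interval 4.17 to 17.8). On chromosomes, the highest fold was 6.30, at peaks643 on NC_025997.1 (1302663 to 1302914), followed by 6.09 at peaks461 on NC_025995.1 (40134238 to 40134652). Folds of 5.96 were found both at peaks23 on NC_025993.1 (12361489 to 12361706) and at peaks1009 on NC_026000.1 (5146969 to 5147213), and a fold of 5.74 at peaks1276 on NC_026003.1 (4196085 to 4196418). At these depths the interval of a single ratio spans several-fold, as at peaks461, whose ratio of 7.92 rested on 22 against 6 fragments (3.11 to 23.9). Picking peaks by the highest fold favours ratios that are too high, and the intervals do not allow for it.

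Peaks at sites where the input was close to its genome-wide level numbered 1327 (16.8%, expected pileup at most 2 times that level). Their median fold was 3.71, with 5th and 95th percentiles of 2.84 and 5.29, on a median pileup of 14 fragments. They included 108 of the 135 peaks with a fold of at least 5. Of the 1327, 350 (26.4%, 24.0 to 28.8%) were on chromosomes.

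Chromosome and scaffold peaks differed in input level and slightly in fold. The median expected pileup was 7.47 times the genome-wide level on chromosomes (bootstrap 95% interval 7.08 to 8.46, n = 1711) and 9.64 times on scaffolds (9.24 to 10.03, n = 6208), with a permutation p of 0.0001, the smallest possible, and an adjusted p of 0.00035. The median fold was 2.76 (2.71 to 2.80) on chromosomes and 2.64 (2.62 to 2.66) on scaffolds, a difference of 0.12 with the same p and adjusted p. Averaged over the 10 bins of expected pileup, the difference in fold was 0.0073 (permutation p = 0.65). Median −log10 q was 6.29 on chromosomes and 6.86 on scaffolds (permutation adjusted p = 0.040), and median widths of 270 and 274 bp did not differ by the test (permutation adjusted p = 0.29).

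No chromosome held more or fewer peaks than even placement by the test. The density over the 16 was 2.65 peaks per Mb, from 2.23 on NC_026002.1 to 3.45 on NC_026006.1. NC_025994.1 had the most peaks, 188, where even placement gave 172.9 ± 12.5 (SD over draws). The smallest adjusted p of the position permutation test was 0.31, and 2 chromosomes had an unadjusted p under 0.05. NC_026006.1 had 79 peaks against 60.7 ± 7.57 placed (position permutation p = 0.019), and NC_026004.1 had 93 against 75.8 ± 8.61 (p = 0.048). The densest stretch of 1 Mb held 12 peaks, on NC_025998.1 between 14065076 and 14925270, and even placement gave at least as many somewhere on the chromosomes often enough that it did not pass (position permutation p = 0.13 over 1000 draws).

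**Figure D3:**
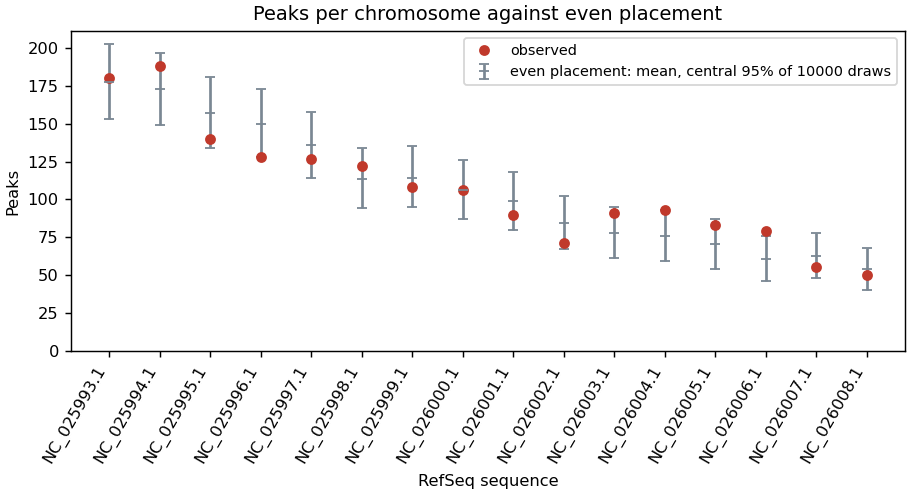
Peaks on each of the 16 chromosome sequences (red points) with the mean and central 95% of 10000 even placements (grey bars). NC_026004.1 and NC_026006.1 lie at or above the upper end of their bars, with 93 and 79 peaks.

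Median fold differed between chromosomes in 1 case. On NC_025993.1 it was 3.09 (bootstrap 95% interval 2.88 to 3.23, n = 180), against 2.73 (2.68 to 2.79, n = 1531) over the other chromosomes, and among the 16 it was the one to pass the permutation test (adjusted p = 0.0032). Its expected pileup had a median of 5.60 times the genome-wide level against 8.06 elsewhere (permutation p = 0.041, not adjusted over the 16 chromosomes). The chromosome was picked by its fold, which is linked to expected pileup, so this p is not an independent test. The difference in fold was 0.36, and 0.14 when averaged over the 10 bins of expected pileup, which did not pass over the 16 chromosomes (permutation adjusted p = 0.22, unadjusted 0.014).

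Peaks lay closer together than even placement gave. Over the 486 sequences with 3 or more peaks (3850 peaks), the median distance to the nearest other summit was 46169 bp, against 66476 ± 2029 bp placed (SD over draws), a ratio of 0.69 (position permutation p = 0.0001, the smallest that 10000 draws can give). On chromosomes alone it was 97687 bp against 133178 ± 5364 bp. Neighbouring chromosome summits were under 1000 bp apart in 52 of 1695 cases, where even placement gave 4.54 on average and 13 at most over 1000 draws, and under 10000 bp apart in 210 cases against 43.9 on average and 64 at most (position permutation p = 0.001 each, the smallest possible). Whether close pairs were separate sites or parts of 1 enriched region called as several peaks was not tested. Even placement also covered any N bases within the spans, so the excess does not by itself show clustering of binding sites. The 393 chromosome peaks with a neighbour within 10000 bp had a median expected pileup of 8.85 times the genome-wide level, against 7.28 for the other 1318, which did not pass the adjusted test (permutation adjusted p = 0.070). Among the 1327 peaks with an expected pileup of at most 2 times the genome-wide level, the ratio was 0.96 (position permutation p = 0.61), on 420 peaks of 36 sequences.

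**Figure D4:**
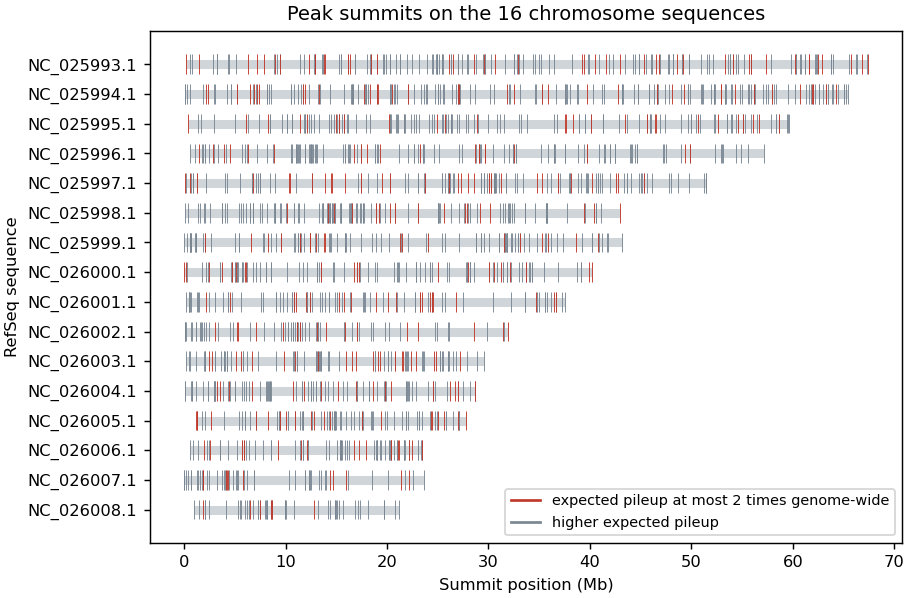
Summits (vertical ticks) along the 16 chromosome sequences in Mb, in red where the expected pileup was at most 2 times the genome-wide level (350 peaks) and in grey elsewhere. The 350 make up part of the 1711 summits drawn.

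Fold enrichment fell slightly with peak width. Across the 7919 peaks, the Spearman rho was -0.18 (permutation p = 1e-05, the smallest that 100000 permutations can give). With −log10 q in place of fold, the rho was 0.17, with the same p. Within the 10 bins of expected pileup the mean rho of fold and width was 0.0022 (permutation p = 0.85), over bins that went both ways: the rho was 0.15 in bin 1, where the input was lowest, and 0.061 in bin 10, against -0.070 in bin 8 and -0.099 in bin 9. The rho of single bins was not tested.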

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

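Of the 7919 peaks, 4873 had a −log10 q of at least 5, 135 had a fold of at least 5, and 1711 lay on chromosomes. Merging overlapping intervals left 7919. Restricting the list to an expected pileup of at most 2 times the genome-wide level, an alternative chosen after seeing the data, left 1327. No chromosome passed the placement test with a −log10 q of at least 5 or, chosen after seeing the data, with an expected pileup of at most 10 times the genome-wide level. Merging changed nothing, and a fold of at least 5 left 30 chromosome peaks, so these settings do not test it. The ratio of observed to placed distance between neighbours was 0.64 with a −log10 q of at least 5 and, in tests chosen after seeing the data, 0.73 on chromosomes alone and 0.75 with an expected pileup of at most 10 times the genome-wide level, each past the test. It no longer passed the test with a fold of at least 5 (0.66, position permutation p = 0.18), where 16 peaks on 5 sequences were left, or with an expected pileup of at most 2 times the genome-wide level (0.96, position permutation p = 0.61), where 420 peaks were left. The correlation of fold with width reversed with −log10 q in place of fold (0.17) and was 0.0022 as a mean within the 10 bins of expected pileup, which ran from -0.099 to 0.15; the cause was not tested for the first, and the second is weighed among the other observations. It stayed negative with a −log10 q of at least 5 and, in a test added after, on chromosomes alone. The difference in median fold between chromosomes and scaffolds fell from 0.12 to 0.0073 when averaged over the 10 bins of expected pileup. It no longer passed the test there (permutation p = 0.65), so its direction is not told. With a −log10 q of at least 5 the difference was 0.069, higher on chromosomes, and still passed. The higher fold on NC_025993.1 fell from 0.36 to 0.14 with that averaging and no longer passed over the 16 chromosomes (permutation adjusted p = 0.22). No paired analysis was possible because each group has 1 sample, and none was left out in turn for the same reason. Other settings set out for gene features, CArG boxes, 6-base words and gene lists were not run. Depth limits single folds at low input, where a pileup of 10 to 34 fragments stood against an expected 2.36 to about 2 times as many.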

Other observations

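The tests of the input window and of the expected pileup were chosen after the pileups had been recovered. The test on input windows was written after its result was seen, and the others before, except that the rise lengths and the redraw at the highest base were added last.

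At most summits the input was raised against the genome-wide level taken here. The length of an even rise was tested only for chromosome peaks with much input. On chromosomes, among the 745 peaks with an expected pileup over 10 times the genome-wide level, the fragment-size window gave the largest expected value for 738 (99.1%, exact 95% interval 98.1 to 99.6%). An input raised evenly over 10 kb leads to 42.8% with counting noise alone, so the tables argue against an even rise of that length for these 745 peaks. Long sequences collapsed in the assembly are not ruled out, since their coverage need not be even. Scaffold peaks and peaks with less input were not tested. Even rises with the summit anywhere in them gave 97.9% for a length of 500 bp, 91.8% for 1000 bp, 70.3% for 2000 bp, 58.0% for 5000 bp and 53.6% for 10000 bp. What stays open for these peaks is a short rise, whose length these simulations do not fix, or a longer uneven one. For a short rise, short sequences present in more copies than in the assembly are a candidate explanation. Sites that shear or amplify well in both libraries are another. None of these was tested, since they need the sequence, and the design gives no biological contrast for the input.

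Folds were lower where the input was higher, and the calling limit together with counting noise of the immunoprecipitate was tested as the whole cause. Redrawing the folds of the highest of the 10 bins at the input levels of the lowest gave a median of 3.28, below the observed 3.87 (3.87 to 3.90). Taking the highest base of each peak's width in the redraw raised it to 3.44, still below. The limit and immunoprecipitate noise therefore did not account for the whole difference if sites of all input levels share the folds of the highest bin. The redraw held each expected pileup fixed, so counting noise of the input was not tested. The bins were cut on that same expected pileup, so input noise may be the remaining part. That sites with little input hold other folds is another possibility, and both stay open with 1 library per group.

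The fall of fold with width may follow in part from the input level. Expected pileup rose with width (Spearman rho 0.25 across peaks, permutation p = 0.0001, the smallest possible), and within the 10 bins of expected pileup the mean rho of fold and width was 0.0022, where the overall value was -0.18. The bins were not alike, from -0.099 in bin 9 to 0.15 in bin 1, so the mean argues against a fall shared by all bins and does not show that fold and width are unrelated within them. Why the bins differ stays open. The calling limit also narrows the range of folds within a bin, and this was not separated from the input level.

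The hypothesis that peaks with little input lie nearer the ends of chromosomes was not borne out. The outer 10% at each end of the spans held 76 of 350 peaks with an expected pileup under 2 times the genome-wide level (21.7%, 17.5 to 26.4%) and 144 of 745 over 10 times (19.3%, 16.6 to 22.4%), with a Fisher exact p of 0.37, a test used in place of the permutation first set for it.

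Among the 1327 peaks with little input, closer spacing than even placement was not detected, and this may come from their number. Their ratio of observed to placed distance, 0.96 on the 420 peaks of sequences with 3 or more, lay inside the central 95% of 200 random subsets of 1327 peaks from the whole list (0.74 to 1.11, median 0.91), and 57 of the 200 were at least as high. These data therefore do not show that peaks with little input are spaced differently from the rest.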
